A study of Mus musculus with 12 samples.

How the data were processed

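Total RNA from the left ventricles of Balb/c mice was measured on 12 Affymetrix arrays of 1 colour, with 5 µg of RNA as input per the labels. Every array is a group of its own, so the number of replicates per group is 1. The groups are TAC at 1 day, 1 week and 1 month, MI at 1 week and 1 month, Ang II at 1 week, and a control array for each. The deposited values are intensity, a linear probe-set signal for each probe set and array, and the submitters' processing notes name GCOS, with no version. The signal algorithm and any scaling by the authors are not given in the sources used here. Whether an array holds RNA from 1 animal or from a pool, and of how many, is not stated either, so p-values measure only the spread between these arrays, part of which may be technical.

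Each procedure array was paired with the control of the same series and time. The pairing comes from the sample titles, which name the series of each sham, and no other label repeats it. The series text gives a 1 day harvest to MI, whereas the array labels give it to TAC, and the array labels were used. The series text describes a coronary occlusion of 30 min followed by reperfusion, whereas the array labels name only a ligation, and values are reported under the name MI.

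Choices made before the data were examined were the groups, the pairs, the tests, the thresholds, the gene lists and the rule for named genes. The 2% trimmed means of the 12 arrays lay between 105 and 131 and so differed by more than the tolerance of 5%. The signals were therefore scaled to a common trimmed mean, with factors from 0.872 to 1.09. Signals under the 20th percentile of all values (a signal of 4.54) were raised to it, and log2 was taken. In the deposited table the values of the TAC 1 day array carry 6 decimals and those of the other arrays 1.

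Of 45101 probe sets, 34958 were listed with exactly 1 gene symbol in the platform's annotation, 932 with several and 9211 were not listed. The Entrez gene identifiers of 34754 of these were found in the RefSeq mouse gene table, and 0 symbols differed from it. Each gene was represented by its brightest probe set, and genes with a mean log2 above the 40th percentile of named probe sets (a signal of 18.1) were tested, which left 11624 genes. The floor held 0.183% of the tested values. Genomic positions of the probe sets are not used here. No depth can be given for arrays, whose number limits the precision.

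Models were fitted in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, with the pair as a block, an intensity trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. The common response is the mean change over the 6 pairs, with 5 residual degrees of freedom. A second fit gave separate effects for TAC (3 pairs), MI (2 pairs) and Ang II (1 pair) and the TAC minus MI difference, with 3 residual degrees of freedom, so the lone Ang II pair is assumed to vary like the others. The residual holds real differences between procedures and times as well as noise. Changes are log2 ratios of procedure to control with the standard error of the fit.

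A single pair was not tested on its own, apart from the Ang II effect above, whose spread comes from the other pairs. A gene was counted as 2-fold when its log2 ratio was at least 1 in size, the brighter value was above the median signal of all arrays (25.9) and the procedure array lay outside the range of the 6 controls. The background uses the same ratio and signal limits between control arrays of the same time, 4 pairs read in both directions, which makes 8 comparisons. There the array read first had to lie outside only the other controls rather than all 6, which is easier to pass. Each control pair also joins arrays of different series, whereas each procedure pair is within a series.

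The 38 gene lists cover fetal and hypertrophy genes, sarcomere, calcium handling and ion channels, extracellular matrix, matrix remodelling, metabolism, stress and inflammation, and markers of other cell types and neighbouring tissues. Of these, 37 had at least 4 measured members and were tested. The list of thymus markers, with 2 measured members, was not tested. Lists were tested with camera in the common fit with a preset inter-gene correlation of 0.01, and again with an estimated correlation. An exact two-sided sign-flip test of the list median over 64 sign patterns was added, whose smallest possible p is 0.03125. Medians of a list in single pairs were also ranked among 10000 random lists matched on expression (seed 20), as description only.

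Named genes follow a fixed rule. For the common response it takes the 10 largest rises and 10 largest falls among genes past the threshold with 1 direction in all 6 pairs. For each pair it takes the 8 highest and 6 lowest log2 ratios among the 2-fold genes. For each list it takes the 3 members with the largest mean change, or the largest change in a pair, and for the first list all measured members. For TAC alone and MI alone it takes the 6 largest in each direction past the threshold, and for TAC minus MI the 5 largest past it. Symbols without a gene name were skipped. A gene named outside the rule is said to have been chosen after its values were seen.

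Alternatives tried were quantile normalization, floors at the 10th and 40th percentile, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, no block, leaving out each pair, a prior without an intensity trend, robust moderation, an unmoderated fit, other controls, a 1.5-fold threshold and no control range. Signals as deposited, and probe sets of a mean signal above 5000 used only where a gene has no other, were alternatives chosen after seeing the data.

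The fits were tested on simulated data with 50 changed genes at each size. The common fit recovered 34% of changes of 0.5 on the log2 scale, 84% of changes of 1, 100% of changes of 2 and 100% of changes of 3. The TAC effect recovered 10%, 76%, 98% and 100% of these sizes, and the MI effect 4%, 62%, 94% and 100%. The Ang II effect recovered 8%, 28%, 74% and 92%, and the TAC minus MI difference 2%, 24%, 86% and 90%. Among all calls in these simulations, 10 of 169, 7 of 149, 8 of 138, 5 of 106 and 13 of 114 were unchanged genes, in the same order. With no changed gene, limma called 0 genes in the common fit. The 2-fold rule recovered 4%, 42%, 91.3% and 99.3% of these sizes and called 1.53% of unchanged genes. A simulated list of 30 genes shifted by 0.4 gave a camera adjusted p of 3.38e-34, or 6.8e-05 with an estimated correlation, and an unshifted list gave 0.952. The simulated noise was independent between genes, whereas the estimated correlation within real lists reached 0.66 (macrophage markers). The simulation therefore does not show how camera behaves on such lists.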

Results

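Gene expression in the mouse left ventricle was compared across 3 models of cardiac hypertrophy and failure. The mice were Balb/c animals aged 6 to 8 weeks. In transverse aortic constriction (TAC) a narrowed aorta raises the load on the left ventricle. In myocardial infarction (MI) a coronary artery is closed, and angiotensin II (Ang II), a hormone that raises blood pressure, was infused at 2 mg/kg/day. TAC was sampled at 1 day, 1 week and 1 month, MI at 1 week and 1 month, and Ang II at 1 week. Each of these 6 groups and each of its 6 controls was a single array, so no group had a replicate. The 12 arrays each held 45101 probe sets, with trimmed mean signals from 105 to 131, and their number limits the precision. The actin 3' to 5' signal ratio, a measure of RNA integrity, lay between 1.18 and 1.33 on all arrays, and that of Gapdh between 0.790 and 0.854. The 5' to 3' ratios of the array control probes dap and thr ran from 0.222 to 0.611 and from 0.251 to 0.805. They were highest on the TAC 1 day and Ang II arrays and the controls of these. Values are log2 ratios of procedure to control. The ± gives the standard error of limma's fit, for a mean of 6 pairs unless another number is stated. Its variance is moderated across genes and is not the spread of the pair values of that gene alone.

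The first question was which genes changed in the mean of the 6 pairs, 3 of TAC, 2 of MI and 1 of Ang II. Such a mean does not show that each of the 3 models shares a change. Over the mean of the 6 pairs, genes of the extracellular matrix and of the fetal cardiac program were higher, and genes of mitochondrial fuel use were lower, although with Ang II the medians of fatty acid oxidation (-0.039) and oxidative phosphorylation (-0.050) were smaller than differences between controls (up to 0.14 for each). The lists of matrix, fetal, fatty acid oxidation and oxidative phosphorylation genes each had an adjusted p = 0.312 with an estimated correlation. Postn, a matrix protein of activated fibroblasts, rose by 2.27 ± 0.20 (adjusted p = 0.00239). Nppa, the atrial natriuretic peptide, rose by 1.96 ± 0.25 (adjusted p = 0.00428), and Myh7, the slow fetal myosin heavy chain, by 1.75 ± 0.33 (adjusted p = 0.015). Acot1, an acyl-CoA thioesterase, changed by -1.14 ± 0.22 (adjusted p = 0.0161) and Kcnip2, a subunit of the transient outward potassium channel, by -0.87 ± 0.19 (adjusted p = 0.023). All of these had 1 direction in 6 of 6 pairs.

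Among the 10 largest rises with the same direction in all 6 pairs, Mfap4, a microfibril protein, rose by 4.07 ± 0.58 (adjusted p = 0.00621), Cthrc1, a collagen triple helix protein, by 3.19 ± 0.61 (adjusted p = 0.0152) and Ltbp2, which binds microfibrils, by 2.97 ± 0.34 (adjusted p = 0.00327). The sizes for Mfap4 and Cthrc1 depend on the floor, since Mfap4 was at it in 2 and Cthrc1 in 3 of the 6 controls. Mfap4 was at 4.24 with the floor at the 10th and 3.45 with it at the 40th percentile, and Cthrc1 at 3.45 and 2.03. Lox, which cross-links collagen, rose by 2.91 ± 0.37 and Timp1, an inhibitor of matrix proteases, by 2.39 ± 0.47. Nmrk2, a muscle kinase of NAD synthesis, rose by 2.51 ± 0.27, Ecrg4 by 2.57 ± 0.45, the transcription factor Egr2 by 2.41 ± 0.36, and Trem2, a receptor of macrophages, by 2.37 ± 0.39. Egr2 and Trem2 were each at the floor in 1 control. With the floor at the 10th and 40th percentile Egr2 was at 2.63 and 1.81, and Trem2 at 2.43 and 1.31. The 10 largest falls were smaller in size. Dnah8, a dynein heavy chain, changed by -1.59 ± 0.28 (adjusted p = 0.0123), the water channel Aqp6 by -1.54 ± 0.23, Cphx3 by -1.44 ± 0.39 (not past the threshold with the floor at the 40th percentile) and Penk, the enkephalin precursor, by -1.42 ± 0.22. Ces1d, a carboxylesterase, changed by -1.27 ± 0.18, Ttll1 by -1.27 ± 0.23, Ift81 by -1.22 ± 0.18, the receptor Gpr22 by -1.22 ± 0.30, Efnb3 by -1.20 ± 0.24 and Ano10 by -1.20 ± 0.17.

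Of 11624 genes, 1262 passed limma's paired fit, 600 higher and 662 lower, and 1088 of them had 1 direction in all 6 pairs (506 higher and 582 lower). At an unadjusted p under 0.05 there were 3368. With signals as deposited the count was 800, split into 692 higher and 108 lower. With that setting the median of all genes was -0.23 in the TAC 1 day pair, 0.21 in TAC 1 week, 0.31 in TAC 1 month and 0.16 in MI 1 week. The count depended on the moderation of the variance and on the genes tested: limma called 241 genes without an intensity trend, and 0 without moderation (2793 at an unadjusted p under 0.05) or without the filter on dim genes (3703). It was 694 with the mean of all probe sets, 473 without the block, and 267, 295, 256 and 292 without the TAC 1 week, TAC 1 month, MI 1 week and MI 1 month pairs. Without the TAC 1 day pair it was 1255, and without the Ang II pair it rose to 1485.

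**Figure D1:**
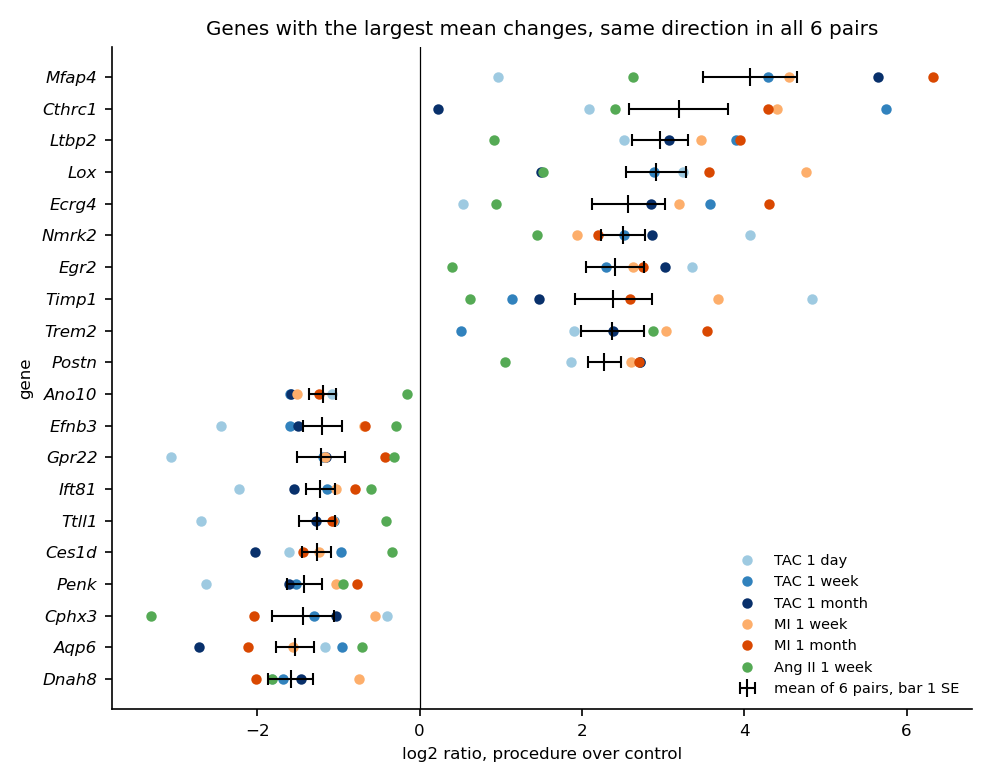
Log2 ratios of procedure to control in each of the 6 pairs (points) for genes with the largest mean changes over the 6 pairs, with the mean and bars of 1 SE. Mfap4 has a mean of 4.07, with 2 of its controls at the floor, and Dnah8 one of -1.59.

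Fetal and hypertrophy genes, which the stressed adult heart is known to express again, rose as a list: 13 of 23 measured members passed, 13 higher and 0 lower, with 16 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.5e-09). The list had adjusted p = 0.312 with an estimated correlation. Besides Nppa and Myh7, Ccn2, a matricellular growth factor, rose by 1.81 ± 0.17, Tubb2b, a tubulin, by 1.25 ± 0.33, the metallothionein Mt2 by 1.14 ± 0.27, Uchl1 by 1.10 ± 0.31 and Rcan1, a calcineurin target, by 1.07 ± 0.20. Smaller rises were those of Fhl1 (0.92), Vim (0.63), Enah (0.61), Tuba1a (0.47), Nppb (0.37) and Des (0.30). Members that did not pass were Flnc (0.81), Nes (0.60), Xirp1 (0.42), Mt1 (0.39), Mybpc2 (0.38), Ankrd1 (0.15), Acta1 (0.055), Csrp3 (-0.020), Actc1 (-0.15) and Acta2 (-0.23). The Csrp3 value turned positive with signals as deposited and after quantile normalization. Nppb, Acta1 and Ankrd1 were among 152 genes brighter than a signal of 5000, on a scale whose highest value was 14795. Of the probe sets of Atp2a2, the calcium pump of the sarcoplasmic reticulum, the brightest had a mean log2 ratio of -0.15, 2 dimmer ones -0.58 each and the dimmest -0.13. The brighter probe set of Col3a1 had 1.09 and the dimmer 2.09, whereas for Col1a1 the brighter had 1.82 and the dimmer 1.60.

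Matrix and fibroblast genes rose as lists. Among collagens and other matrix genes 28 of 35 measured members passed, 28 higher and 0 lower, with 32 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.79e-26; adjusted p = 0.312 with an estimated correlation). Pair medians ran from 0.48 with Ang II to 1.82 in MI 1 week, and controls differed by up to 0.20. In matrix remodelling and TGF-beta genes 15 of 30 measured members passed, 15 higher and 0 lower, with 23 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.36e-13; adjusted p = 0.312 with an estimated correlation), and Mmp12, an elastase of macrophages, rose by 2.05 ± 0.57 (adjusted p = 0.0467), a call lost with the floor at the 40th percentile. The Mmp12 signal was lower than in the sham in TAC 1 week (44.8 against 54.3). It was at the floor in both arrays of TAC 1 month, and higher in the other pairs. For fibroblast and myofibroblast markers 10 of 21 measured members passed, 9 higher and 1 lower, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.9e-07; adjusted p = 0.312 with an estimated correlation). Col1a1, a chain of fibrillar collagen, rose by 1.82 ± 0.27 and Mfap5 by 1.66 ± 0.19, while the scavenger receptor Scara5, named after its value was seen, changed by -0.67 ± 0.16. The fibroblast median was 0.017 in TAC 1 day, where it turned negative (-0.14) with signals as deposited, and 0.45 to 0.99 in the other TAC and MI pairs.

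Macrophage and acute phase genes rose as lists, with their highest medians in TAC 1 day and MI 1 week. For macrophage and monocyte markers 15 of 27 measured members passed, 15 higher and 0 lower, with 26 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.66e-14; adjusted p = 0.312 with an estimated correlation). Lgals3, galectin-3, rose by 1.97 ± 0.53 (adjusted p = 0.0445) and Ccr2, a chemokine receptor of monocytes, by 1.96 ± 0.32. Macrophage medians were 1.54 in TAC 1 day, 1.69 in MI 1 week and 1.00 in MI 1 month. They were 0.27 in TAC 1 week, 0.42 in TAC 1 month and 0.13 with Ang II, inside the difference between controls of up to 0.82. In acute phase and complement genes 5 of 15 measured members passed, 5 higher and 0 lower, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.71e-06; adjusted p = 0.312 with an estimated correlation). Hp, haptoglobin, rose by 2.27 ± 0.56 (adjusted p = 0.0343), the serum amyloid Saa3 by 1.92 ± 0.54 (adjusted p = 0.0479) and the protease inhibitor Serpina3n by 1.72 ± 0.33, and the medians of this list in the 4 pairs other than TAC 1 day and MI 1 week lay inside the difference between controls of up to 0.94. Of cytokines and chemokines, 1 of 18 measured members passed, 1 higher and 0 lower, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.398 with an estimated correlation). The member that passed was the chemokine Ccl8 (0.92 ± 0.25, adjusted p = 0.0445), named after its value was seen, while Ccl2 (1.67, adjusted p = 0.0581), Ccl12 (1.20) and Ccl9 (1.15) did not pass. Among neutrophil markers 0 of 6 measured members passed, 0 higher and 0 lower, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0287; adjusted p = 0.448 with an estimated correlation). S100a9 (1.67), Lcn2 (1.01) and S100a8 (0.96) led this list, in which controls of 1 time differed by up to 2.31. The neutrophil call was lost without the TAC 1 day pair (adjusted p = 0.129), without the MI 1 week pair (0.0946) and without the block (0.0688).

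Immediate early genes, transcription factors induced within minutes of a stimulus, rose as a list: 12 of 24 measured members passed, 12 higher and 0 lower, with 20 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.32e-11; adjusted p = 0.312 with an estimated correlation). Egr3 rose by 1.79 ± 0.22 and Fos by 1.77 ± 0.50 (adjusted p = 0.0494), beside Egr2. Fos had a lower signal than its control in TAC 1 week (210 against 233) and with Ang II (97.4 against 118), and a higher one in the other pairs. For cell cycle genes 6 of 22 measured members passed, 6 higher and 0 lower, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.76e-06; adjusted p = 0.312 with an estimated correlation). Prc1, a protein of the dividing spindle, rose by 1.64 ± 0.34, the kinase Cdk1 by 1.5 ± 0.28 and the proliferation marker Mki67 by 1.30 ± 0.37 (adjusted p = 0.0493). Prc1, at the floor in 1 control, was at 1.81 and 1.18 with the floor at the 10th and 40th percentile. The cell cycle median was 1.35 in TAC 1 week, 0.68 in TAC 1 month and 0.81 in MI 1 week, and inside the difference between controls of up to 0.58 with Ang II (0.17), in MI 1 month (0.26) and in TAC 1 day (0.12), where it was negative (-0.031) with signals as deposited. Among glucocorticoid-responsive genes 6 of 19 measured members passed, 4 higher and 2 lower, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.448 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, rose by 1.01 ± 0.21 and Mt2 by 1.14 ± 0.27, Gadd45g was at 1.10 without passing, and Klf15, a glucocorticoid-induced factor of the heart, changed by -0.47 ± 0.13 (named after its value was seen). This call was lost without the block (adjusted p = 0.0916), and the Ang II median turned positive (0.0038) after quantile normalization. Of atrial chamber markers 3 of 9 measured members passed, 3 higher and 0 lower, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00787; adjusted p = 0.448 with an estimated correlation), and the call was lost with the mean of all probe sets (0.0542). Besides Nppa, the calcium pump regulator Sln rose by 1.38 ± 0.32 (adjusted p = 0.0274) and Dkk3 by 1.32 ± 0.30 (adjusted p = 0.0257).

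Genes of energy metabolism fell together. In oxidative phosphorylation and the TCA cycle 33 of 45 measured members passed, 0 higher and 33 lower, with 0 higher and 45 lower adjusted over the list alone and 29 brighter than a signal of 5000 (camera adjusted p = 1.06e-20; adjusted p = 0.312 with an estimated correlation). Idh2, a mitochondrial isocitrate dehydrogenase, changed by -0.42 ± 0.093, Cox7a1, a heart subunit of cytochrome oxidase, by -0.40 ± 0.067 and Suclg1 by -0.37 ± 0.063. For fatty acid oxidation 22 of 33 measured members passed, 0 higher and 22 lower, with 1 higher and 29 lower adjusted over the list alone (camera adjusted p = 7.21e-15; adjusted p = 0.312 with an estimated correlation). Ppara, the nuclear receptor that drives these genes, changed by -0.72 ± 0.14 and Ucp3 was at -0.69 without passing (adjusted p = 0.0799). In ketone and branched-chain amino acid use 14 of 19 measured members passed, 0 higher and 14 lower, with 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 8.47e-13; adjusted p = 0.312 with an estimated correlation). Dbt changed by -0.61 ± 0.11, Mmut by -0.60 ± 0.086 and Aldh6a1 by -0.60 ± 0.080, all enzymes of that catabolism. Fatty acid oxidation medians lay between -0.51 and -0.33 in the 5 TAC and MI pairs and at -0.039 with Ang II, and controls differed by up to 0.14. Over the same 6 pairs the medians of other cell types ran from 0.017 to 0.99 for fibroblast and from 0.13 to 1.69 for macrophage markers. Genes of glucose metabolism fell as a list, but not in every member: 8 of 26 measured members passed, 2 higher and 6 lower, with 4 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.398 with an estimated correlation). Its call was lost after quantile normalization (adjusted p = 0.471), and with signals as deposited its median turned positive in TAC 1 week (0.022), TAC 1 month (0.10) and MI 1 week (0.0018). The glycolytic enzyme Pfkp rose by 0.69 ± 0.083 and Pgd of the pentose phosphate pathway, named after its value was seen, by 0.48 ± 0.11. Pdk2, a kinase that inhibits pyruvate dehydrogenase, changed by -0.53 ± 0.10, and the glucose transporter Slc2a4 was at -0.64 without passing.

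Calcium handling and ion channel genes fell as a list: 7 of 20 measured members passed, 0 higher and 7 lower, with 1 higher and 15 lower adjusted over the list alone (camera adjusted p = 7.53e-07; adjusted p = 0.312 with an estimated correlation). Kcnip2, Kcnd2 (-0.84 ± 0.18) and Kcnj3 (-0.79 ± 0.21) carry potassium currents or regulate them, and in TAC 1 day these 3 genes were at -2.07, -1.90 and -2.12. Sarcomere genes, 14 of them brighter than a signal of 5000, fell as a list: 3 of 17 measured members passed, 0 higher and 3 lower, with 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 4.65e-05; adjusted p = 0.398 with an estimated correlation). Tcap, which caps titin, changed by -0.40 ± 0.086, Ldb3 of the Z disc by -0.34 ± 0.082 and Pln, phospholamban, by -0.23 ± 0.061. Pln is on this list but regulates the calcium pump and is not a sarcomere protein. The sarcomere call was lost after quantile normalization (adjusted p = 0.649), and its TAC 1 month median of -0.24 turned to 0.021 there and to 0.073 with signals as deposited.

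Further lists did not pass camera. Smooth muscle and pericyte markers (adjusted p = 0.732) had 3 members higher, with Cnn1 at 1.56 ± 0.25 and Tagln at 0.89 ± 0.17, and 2 lower, with Abcc9 at -0.59 ± 0.095. Endothelial markers (adjusted p = 0.739) had Plvap higher (0.97 ± 0.26), Flt1 lower (-0.44 ± 0.093) and Cldn5 at 0.42 without passing. In the oxidative stress list (adjusted p = 0.124) 7 members rose and 4 fell, with 8 higher and 6 lower adjusted over the list alone, among them Ncf1, a subunit of the phagocyte oxidase (1.00 ± 0.23). Of renin-angiotensin-aldosterone and natriuretic genes (adjusted p = 0.911) Ace, the angiotensin converting enzyme, rose by 0.69 ± 0.084 (adjusted p = 0.00354) and the peptidase Mme changed by -0.74 ± 0.20. Hypoxia and angiogenesis genes (adjusted p = 0.617) had Hif1a higher (0.57 ± 0.086), Angpt1 lower (-0.89 ± 0.17) and Hbegf at 0.91 without passing, with a TAC 1 month median of -0.12 that turned to 0.20 with signals as deposited. Mesothelial and epicardial markers (adjusted p = 0.436) included rises of Krt18 (1.83 ± 0.37) and Aldh1a2 (1.21 ± 0.23). The atrophy and proteolysis list (adjusted p = 0.739) held a rise of the protease Ctsk (1.19 ± 0.28). Passing members were Cd28 (-0.77 ± 0.18) among T and B cell markers (adjusted p = 0.732), Slc36a2 (-0.67 ± 0.15) among adipocyte markers (adjusted p = 0.332), Fech (-0.27 ± 0.068) among erythroid markers (adjusted p = 0.703) and Hopx (-0.75 ± 0.10), also a heart gene, among lung markers (adjusted p = 0.617). Camera gave adjusted p = 0.832 for interferon response genes, 0.436 for heat shock, 0.145 for MHC class II, 0.154 for circadian clock and 0.639 for ribosomal protein genes. It gave adjusted p = 0.617 for skeletal muscle markers, 0.639 for conduction and nerve markers and 0.233 for sex-linked genes. The MHC class II list passed without the MI 1 week pair (adjusted p = 0.00297) and the circadian list without the TAC 1 week pair (0.0304) or with signals as deposited (0.0422). Ribosomal protein genes passed after quantile normalization (adjusted p = 0.000198) and with signals as deposited (0.0426).

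Camera called 18 of 37 lists, 12 higher and 6 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.312. The exact sign-flip test gave p = 0.03125, the smallest it can reach, for 17 lists, with 0 after adjustment over lists. These were not all lists that camera called. They included the oxidative stress list and the 4 measured sex-linked genes, but not neutrophil markers, glucocorticoid-responsive genes or atrial markers. Swapping procedure and control within pairs gave at least 18 called lists in 7 of the 32 arrangements, the real one included.

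**Figure D2:**
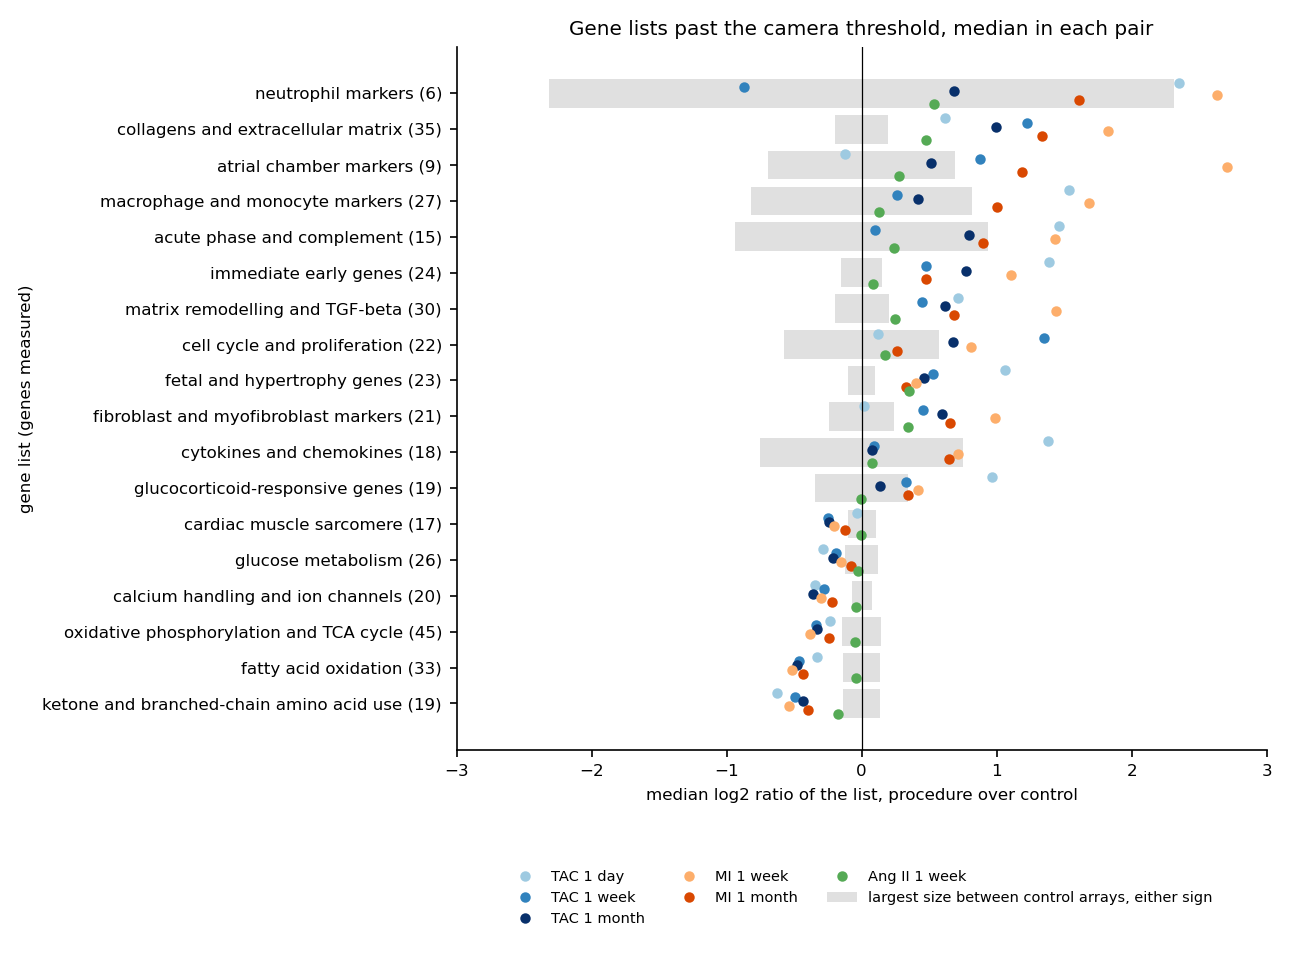
Median log2 ratio of the 18 gene lists past the camera threshold in each of the 6 pairs (points), with a grey band, drawn to both sides of 0, of the largest size between control arrays of the same time. Collagen and matrix genes were above the control band in every pair, from 0.48 to 1.82.

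The TAC pairs, taken alone, asked which genes pressure overload changed over 3 times. Adam12, a membrane metalloprotease, rose by 3.76 ± 0.36 (SE, 3 pairs; adjusted p = 0.00554), Ltbp2 by 3.16 ± 0.27 and Nmrk2 by 3.15 ± 0.27. Adam12 was at the floor in the TAC-series sham at 1 week, and its change was 3.87 and 2.55 with the floor at the 10th and 40th percentile. Egr2 rose by 2.89 ± 0.35 (3.33 and 2.00 with the floor at the 10th and 40th percentile), Lox by 2.54 ± 0.35 and the long noncoding RNA Morrbid by 2.48 ± 0.42. Falls were led by Penk with -1.92 ± 0.24 (adjusted p = 0.0137), Efnb3 with -1.85 ± 0.19, Gpr22 with -1.80 ± 0.36, Ttll1 with -1.68 ± 0.27, Ift81 with -1.64 ± 0.18 and Aqp6 with -1.61 ± 0.31. Of the 23 fetal and hypertrophy genes, 7 passed in TAC, all higher: Nppa (1.92 ± 0.24), Ccn2 (1.97 ± 0.18), Tubb2b (2.03 ± 0.35), Rcan1 (1.39 ± 0.25), Fhl1 (1.04 ± 0.17), Enah (0.84 ± 0.10) and Vim (0.67 ± 0.10). Limma called 272 genes for TAC, 125 higher and 147 lower, with 2509 at an unadjusted p under 0.05. Signals as deposited gave 102 genes, split into 92 higher and 10 lower. The count was 640, 40 and 20 without the TAC 1 day, 1 week and 1 month pairs, and 34 and 36 without the MI 1 week and 1 month pairs, which share the estimate of spread. Without the filter, or without an intensity trend, limma called 0 TAC genes (2677 and 2130 at an unadjusted p under 0.05), with 147 without the block and 75 with the mean of all probe sets.

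One day after TAC, Timp1 was at 4.83, the transcription factor Myc at 4.75, Tnc, the matrix protein tenascin C, at 4.53, and the monocyte chemokines Ccl2 and Ccl12 at 4.32 and 4.29. Cxcr6 (4.49), Cytip (4.24) and the cholesterol hydroxylase Ch25h (4.12) completed the 8 highest 2-fold genes, Cytip against a control at the floor. The 6 lowest were Fbxo44 (-4.08), Mfsd4b1 (-3.96), Cmtm8 (-3.67), Blnk (-3.46), Gsdmcl2 (-3.42) and Klhdc8a (-3.33), and Mfsd4b1, Cmtm8, Blnk and Gsdmcl2 were at the floor after TAC. All 23 fetal and hypertrophy genes had ratios above 0, with a median of 1.06, the highest of the 6 pairs, and 13 were 2-fold higher, Flnc at 2.97 among them. Medians were 1.39 for immediate early genes (controls differed by up to 0.15), 1.38 for cytokines (0.75), 0.97 for glucocorticoid-responsive genes (0.34) and -0.63 for ketone and amino acid use (0.14). Slc2a4, the insulin-responsive glucose transporter, was at -1.92. The pair held 663 higher and 744 lower 2-fold genes, against totals of 244 to 354 between controls, with no replicate check. The spike-in probes of this pair had a log2 ratio of -0.35, against -0.06 to 0.04 in the other pairs. On signals as deposited the split was 499 higher and 1079 lower, and among genes above the 60th percentile the total was 917.

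At 1 week of TAC, collagen and matrix genes had a median of 1.23 and cell cycle genes of 1.35. Cthrc1 was at 5.74, Mfap4 at 4.29, Adam12 at 4.14, Ltbp2 at 3.89, Serpinb1a at 3.83 and Ecrg4 at 3.58, with Ckap2 (3.80) and Prc1 (3.29), which act on the mitotic spindle. Cthrc1, Adam12 and Ckap2 were at the floor in the sham, so their ratios depend on it, and Cthrc1 was at 7.06 and 3.90 with the floor at the 10th and 40th percentile. Mki67 was at 3.23 and Mcm6, a replication helicase subunit, at 3.08. The cell cycle median was the highest of the 6 pairs, and controls differed by up to 0.58. Nppa was at 2.42 and Myh7 at 2.23. The lowest 2-fold genes were Pcsk4 (-3.02), Plxnb3 (-2.98), Cacng7 (-2.95), Slc34a2 (-2.83), Sebox (-2.73) and Abca4 (-2.69), with Slc34a2 at the floor after TAC. The pair held 253 higher and 96 lower 2-fold genes, a total of 349 inside the control range of 244 to 354, though the 253 higher genes exceeded the controls' 67 to 217. The split was 513 higher and 55 lower with signals as deposited, and the total was 128 above the 60th percentile and 525 without the filter.

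At 1 month of TAC, Mfap4 (5.64), Adam12 (3.64), the cartilage matrix protein Comp (3.25), Ltbp2 (3.07) and Egr2 (3.02) were among the 8 highest 2-fold genes, with Btbd19 (3.31), Fgf6 (3.26) and Hspbap1 (3.05). Mfap4 and Hspbap1 were at the floor in the sham, and Mfap4 was at 6.03 and 3.81 with the floor at the 10th and 40th percentile. Tubb2b was at 2.55, Nppa at 2.29 and Idh2 at -0.89. The lowest were Zfp39 (-3.33), Lrp3 (-3.31), the T-type calcium channel Cacna1g (-3.07), Olfr15 (-2.99), Rtbdn (-2.90) and Spata9 (-2.83), and Zfp39, Lrp3, Cacna1g and Rtbdn were at the floor after TAC. Collagen and matrix genes had a median of 0.99 and macrophage markers of 0.42, inside the control range that reached 0.82. There were 222 higher and 147 lower 2-fold genes, a total of 369 where controls reached 354. Without the control range the total was 541, inside the 443 to 558 between controls, as was the SD of 0.501 (0.480 to 0.511). Signals as deposited gave 594 higher and 75 lower, and above the 60th percentile the total was 138.

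**Figure D3:**
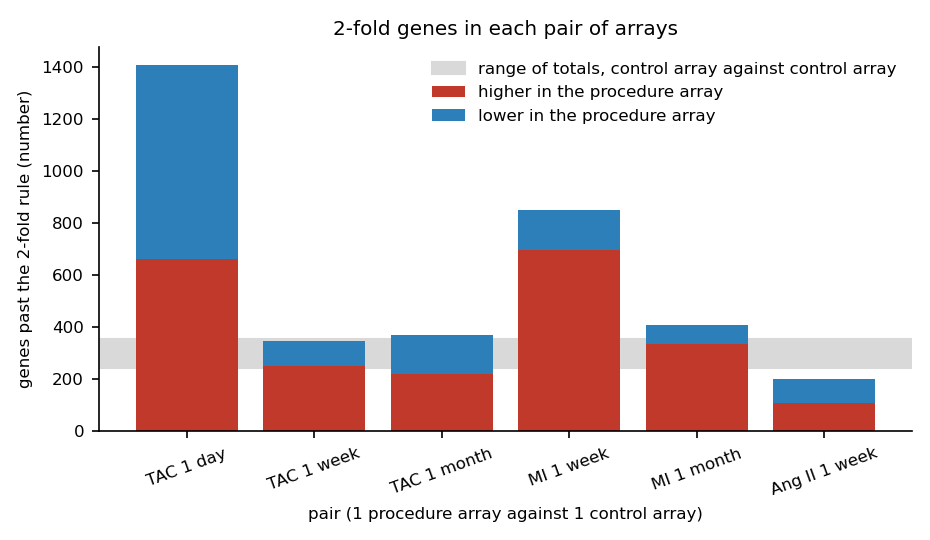
Number of genes at least 2-fold higher or lower in each of the 6 pairs, beside the count between control arrays of the same time. For these the array had to lie outside only the other controls. TAC 1 day (1407), MI 1 week (850), MI 1 month (408) and TAC 1 month (369) stand above the control totals of 244 to 354. TAC 1 week (349) lies inside them and Ang II (200) below.

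The MI pairs, taken alone, asked which genes changed after infarction. Mfap4 rose by 5.43 ± 0.94 (SE, 2 pairs; adjusted p = 0.0472), Hp by 4.40 ± 0.58 (adjusted p = 0.0197), Lox by 4.17 ± 0.43 and Sfrp2, a secreted Wnt modulator, by 3.80 ± 0.57. Mfap4 was at the floor in the MI-series sham at 1 month, and its change was 4.52 with the floor at the 40th percentile and 5.76 at the 10th, where it no longer passed. Ecrg4 rose by 3.75 ± 0.65 and Ltbp2 by 3.70 ± 0.33. The 6 largest falls were those of Ces5a (-1.55 ± 0.25), Ano10 (-1.38 ± 0.17), Abhd1 (-1.35 ± 0.22), Ces1d (-1.34 ± 0.23), Thrsp, a regulator of lipid synthesis (-1.28 ± 0.17), and Acot2 (-1.05 ± 0.16). Of the 23 fetal and hypertrophy genes, 3 passed in MI, all higher: Nppa (2.62 ± 0.30), Ccn2 (2.02 ± 0.22) and Vim (0.86 ± 0.12). Limma called 114 genes, 96 higher and 18 lower, with 2006 at an unadjusted p under 0.05. Signals as deposited gave 121 genes, split into 117 higher and 4 lower. The count was 1495 without the TAC 1 day pair, 65 and 66 without the TAC 1 week and 1 month pairs, 4 without MI 1 month, and 0 without MI 1 week (567 at an unadjusted p under 0.05). Without the filter or the intensity trend limma called 0 (2255 and 1665 at an unadjusted p under 0.05), and 25 without the block or 60 with the mean of all probe sets.

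One week after MI, macrophage markers had a median of 1.69 (controls differed by up to 0.82) and acute phase genes of 1.44 (0.94). Clec4d, a lectin receptor of myeloid cells, was at 5.53, Gpnmb at 5.51, Saa3 at 4.90, Lox at 4.76, Mfap4 at 4.55, Lgals3 at 4.48, Serpinb9b at 4.46 and Hp at 4.43. Clec4d and Serpinb9b were at the floor in the sham, and Clec4d was at 6.85 and 3.69 with the floor at the 10th and 40th percentile. Mmp9, a protease of inflammatory cells, was at 4.41, also against a sham at the floor, and Fos at 4.21. Myh7 (3.75) and Nppa (2.91) had their highest ratios of the 6 pairs here. Collagen and matrix genes had a median of 1.82, matrix remodelling genes of 1.44 and atrial chamber markers of 2.71 (controls differed by up to 0.69), with Sln at 3.51 and the atrial myosin light chain Myl7 at 2.90. The 6 lowest 2-fold genes were Igtp (-3.42), an interferon-induced GTPase, Mpzl3 (-3.25), Mpp2 (-2.99), Ly6d (-2.80), Srms (-2.78) and Foxh1 (-2.77), with Ly6d and Foxh1 at the floor after MI. Interferon response genes had a median of -0.55, with Iigp1 at -3.06 and Gbp3 at -1.72. Igtp and Iigp1 were high in the sham of this pair, above the other 5 controls. The pair held 699 higher and 151 lower 2-fold genes, or 420 in total above the 60th percentile.

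One month after MI, Mfap4 was at 6.32, Hp at 4.37, Ecrg4 at 4.30, Cthrc1 at 4.30, Comp at 4.09 and Sfrp2 at 3.97. Mfap4 and Cthrc1 were at the floor in the sham: with the floor at the 10th and 40th percentile Mfap4 was at 6.97 and 4.49, and Cthrc1 at 4.46 and 2.46. Jchain, which joins antibody chains (4.45), and Car3, a carbonic anhydrase abundant in fat and muscle (4.11), were also among the 8 highest. The immunoglobulin gene Ighm was at 3.86 and the median of the 4 measured T and B cell markers at 2.25. Adipoq, a marker of fat cells, was at 3.80, Trem2 at 3.54 and Nppa at 2.34. The lowest 2-fold genes were Fam184a (-2.99), Adam1a (-2.97), Kcnn1 (-2.95), Pnmt (-2.91), Plxnb3 (-2.91) and Bcl11a (-2.89), and Adam1a, Kcnn1 and Bcl11a were at the floor after MI. There were 336 higher and 72 lower 2-fold genes, or 170 in total above the 60th percentile, and 553 without the control range, inside the 443 to 558 between controls.

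TAC and MI were then compared directly. Interferon response genes were higher in TAC than in MI (camera adjusted p = 8.73e-06), and macrophage markers (1.06e-09), collagen and matrix genes (3.99e-06) and atrial chamber markers (4.64e-05) were higher in MI. These lists each had an adjusted p = 0.587 with an estimated correlation. The TAC effect includes a 1 day pair, a time that MI lacks. Macrophage markers had a higher median in TAC 1 day than in MI 1 month, and controls differed by up to 0.82. The atrial median was by far the highest in MI 1 week, where atrial tissue in the sample stays open. Interferon medians were -0.31, 0.40 and 0.33 in the TAC pairs and -0.55 and 0.077 in the MI pairs, and the MI-series sham at 1 week was high for Igtp and Iigp1. Collagen and matrix medians were 0.62, 1.23 and 0.99 in TAC and 1.82 and 1.34 in MI. In all, 12 lists differed by camera, and 0 with an estimated correlation. Limma called 0 genes for the difference (527 at an unadjusted p under 0.05; smallest adjusted p 0.663), and the simulated test recovered 24% of differences of 1 on the log2 scale.

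Ang II at 1 week had the narrowest spread of log2 ratios of the 6 pairs (SD 0.42). The macrophage genes Mmp12 (3.76), Gpnmb (3.20) and Trem2 (2.87) were among the 8 highest 2-fold genes, with Lrrc18 (3.11), Ccdc136 (3.02), Cyth4 (2.92), the surfactant gene Sftpc (2.87) and Clba1 (2.86). Controls differed in these macrophage genes: Gpnmb had a signal of 136 with Ang II and 14.8 in its control, with 14.8 to 136 over all 6 controls, Mmp12 had 62.2 against 4.60, with 4.54 (the floor) to 55.5, and Trem2 had 42.3 against 5.77, with 4.54 to 25.4. The Clba1 ratio, taken against a control at the floor, turned to -0.18 with the floor at the 10th percentile. Among fetal and matrix genes Nppa was at 0.73, Myh7 at 0.90, Ccn2 at 0.89, Postn at 1.05 and Lox at 1.52. The collagen and matrix median was 0.48 (controls differed by up to 0.20), while oxidative phosphorylation (-0.050) and fatty acid oxidation (-0.039) lay inside the differences between controls, which reached 0.14 for each. The lowest 2-fold genes were Cphx3 (-3.31), Crybg1 (-3.05), Smarca1 (-2.97), Batf (-2.84), Fgf11 (-2.82) and Zfp316 (-2.77), with Crybg1 and Fgf11 at the floor after Ang II. The pair held 110 higher and 90 lower 2-fold genes, a total of 200 below the controls' 244 to 354, and 342 without the control range, 331 without the filter or 16 above the 60th percentile. Limma called 0 genes (284 at an unadjusted p under 0.05).

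**Figure D4:**
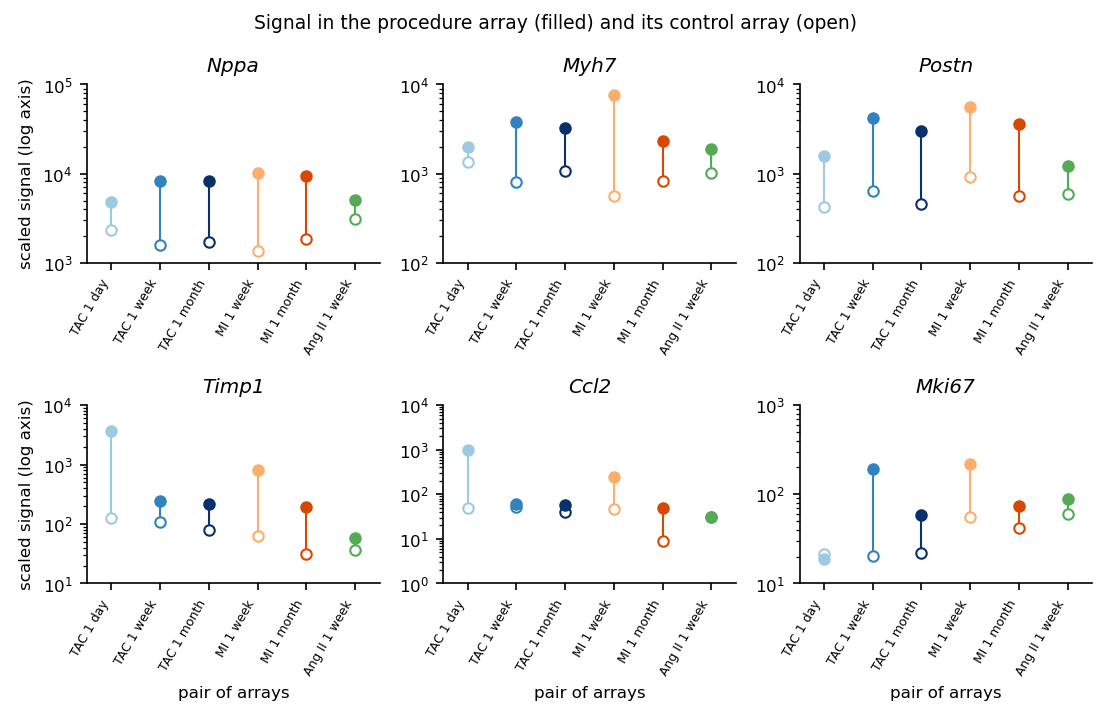
Signals of Nppa, Myh7, Postn, Timp1, Ccl2 and Mki67 on a log axis for each procedure array (filled) and its control (open), 1 array per point. Nppa reached 10204 in MI 1 week, and Postn was above its control in each of the 6 pairs.

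Across all tested genes, the log2 ratios of the 15 combinations of pairs had correlations from 0.14 to 0.49 (Pearson, median 0.30), highest between MI 1 week and MI 1 month, followed by TAC 1 day and MI 1 week with 0.41. The 5 combinations with Ang II, 0.14 to 0.17, were the lowest. Against pairs of control arrays the 16 correlations ran from -0.03 to 0.18 (median 0.07), a range that holds all 5 values of Ang II. These are correlations across genes, which are not independent replicates, and the median was 0.117 without the filter on dim genes.

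The control arrays differed among themselves. In the sham at 1 day after the TAC operation, Lcn2, Acot1, Angptl4, Cdkn1a and Serpina3n were above the other 5 controls, and the array held 54 genes above and 219 below the range of these 5 that were also at least 2-fold from their mean. Gpnmb, S100a9 and S100a8 stood high in the TAC-series sham at 1 week, Igtp, Iigp1 and Irgm2 in the MI-series sham at 1 week, Mmp12 in the TAC-series sham at 1 week and the MI-series sham at 1 month, and Hspa1a and Hspa1b in both MI-series shams. Mfap4 and Cthrc1, which led several pairs, were high in the MI-series sham at 1 week too. The totals of the 5 later controls ran from 117 to 243.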

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

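The swaps for the gene counts of the common response and of TAC, the tests of the TAC 1 day count, those of metabolism other than the sarcomere test, and the test of the Nppa response were chosen only after the result was seen.

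Whether chance arrangements of the arrays could give the reported counts was tested by swapping procedure and control within pairs. For the common response, 1 of 32 arrangements gave as many genes, the real one with 1262, and the highest other gave 0. That is the smallest share the swaps allow, in a test chosen after the count was seen. Chance is argued against for this count but not excluded. The count itself was 0 in limma without the filter and in the unmoderated fit (3703 and 2793 at an unadjusted p under 0.05), where the swaps were not run. For TAC, 1 of 4 arrangements gave as many, with 272 genes in the real one and 0 in the highest other, and the arrangements are too few for a share under 0.05. For gene lists, 7 of 32 arrangements gave at least the 18 lists of the real one, the highest other also giving 18, so chance is not excluded for the number of lists.

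Several lists differed between TAC and MI by camera with a preset correlation, and none of them with an estimated correlation (adjusted p = 0.587 for each). Lists higher in TAC were interferon response (adjusted p = 8.73e-06), heat shock (0.00122), fetal and hypertrophy genes (0.00657), skeletal muscle markers (0.0237) and fatty acid oxidation (0.0413). The fatty acid oxidation median fell in every TAC and MI pair, so that list was only lowered less in TAC. Both MI-series shams were high for the heat shock genes Hspa1a and Hspa1b, and controls differed by up to 0.43 for the heat shock list. Lists lower in TAC than in MI were macrophage markers (adjusted p = 1.06e-09), collagens and matrix (3.99e-06), atrial chamber markers (4.64e-05), fibroblast markers (6.8e-05), acute phase genes (9.54e-05), matrix remodelling (0.00442) and mesothelial markers (0.0289). Macrophage medians were 1.54, 0.27 and 0.42 in the TAC pairs and 1.69 and 1.00 in the MI pairs.

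Opposite directions in all TAC and all MI pairs were found in 4 of 37 lists and 5 of 112 named genes, and the opposite direction itself was not tested. With random and independent signs the share would be 6.25%. That share does not apply to the named genes, some of which were chosen for 1 direction in all 6 pairs. The ratios of the pairs are also correlated, so no conclusion is drawn from it. With signals as deposited none of the 4 lists kept it: the renin-angiotensin list was at 0.16 and 0.23 and the hypoxia list at 0.16 and 0.20 in TAC 1 week and 1 month, the lung list at 0.049 in TAC 1 week and the mesothelial list at 0.13 in TAC 1 month. Mean TAC minus mean MI was -0.33 for the renin-angiotensin-aldosterone and natriuretic list, -0.20 for hypoxia and angiogenesis and -0.53 for lung markers (camera adjusted p for the difference 0.713, 0.296 and 0.129), the other list being that of mesothelial markers. Among genes it was 0.24 for Acta1, the skeletal alpha-actin, 1.08 for Mybpc2, 0.99 for Smarca1, -0.95 for Fgf11 and -2.45 for Spata9 (limma adjusted p = 0.983 for each). Of 3392 probe sets without exactly 1 gene symbol that lay above the signal limit of the tested genes, which no comparison used, 116 passed the common fit (54 higher, 62 lower; 605 at an unadjusted p under 0.05), or 3.42% against 10.9% of named genes.

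Atrial chamber markers had a median of 2.71 in MI 1 week, with Myl7 at a signal of 3747 against 504 in its sham, and 1.19 or less in the other pairs. Atrial tissue in that sample was tested with 11 further atrial genes, of which 7 were measured, 2 of them higher, with a median log2 ratio of -0.18. Differences between controls, set as a bound after the value was seen, reach 0.345 for these genes, the ventricle expresses them too and 2 of them, Kcna5 and Kcnj3, are in the ion channel list, so atrial tissue stays open. Without Nppa the list median in MI 1 week exceeded the next pair by 1.38 (controls 0.556), but Nppa lies near the top of the scale there, so whether these genes follow the size of the Nppa response cannot be told apart from a separate rise. A ventricular change after infarction, which the design names, also stays open and untested.

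The TAC 1 day pair held the most 2-fold genes, 1407 against at most 354 between controls. Brightness of the array is argued against by the count after quantile normalization, 1384 against at most 373 between controls, and noise on dim genes by the count among the 4607 genes of mean signal above 200, which was 436 against 172 in the next pair and at most 30 between controls. RNA quality stays open: the actin 3' to 5' ratios of 1.23 and, in its sham, 1.30 lay inside the 1.18 to 1.33 of the other 10 arrays, but the Gapdh ratio of the sham, 0.854, lay above their highest, 0.839. The control probes dap and thr read transcripts added to the sample, so their ratios do not measure the RNA of the tissue. The 5' to 3' ratio of dap was 0.611 in the TAC 1 day array and 0.574 in its sham. It was 0.497 and 0.550 in the Ang II array and its control, and 0.222 to 0.384 on the other arrays. That of thr was 0.652 and 0.607 in this pair and 0.758 and 0.805 in the Ang II pair, against 0.251 to 0.482. A rapid response to the operation or to overload is a hypothesis, and a fault of this array, deposited with more decimals than the others and with a spike log2 ratio of -0.35 to its sham, or of the sham stays open without a replicate.

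Energy metabolism genes were lower, with fatty acid oxidation medians of -0.33 to -0.51 in the TAC and MI pairs. The scaling applied here is argued against. With signals as deposited the mean of the fatty acid oxidation pair medians was -0.28 and all 6 were below 0 (exact sign-flip p = 0.03125). The Ang II median was only -0.048 there. Any scaling by the authors is not given and could not be tested. A plain loss of myocytes from the sample would raise all other cell types alike. Endothelial minus fibroblast medians averaged -0.56 (SD 0.25, 6 of 6 pairs below 0, exact sign-flip p = 0.03125). Fibroblast markers can also rise by more transcript in each cell, and both list medians were already known. This difference therefore cannot decide whether myocytes were lost. Added cells of other types alone would lower endothelial and metabolic genes alike. Metabolic minus endothelial medians, however, averaged -0.38 (SD 0.15, 6 of 6, exact sign-flip p = 0.03125). The metabolic minus endothelial value argues against added cells of other types acting alone. A loss of myocytes together with more fibroblasts or macrophages was not tested, so a change in cell shares stays open. Measured against sarcomere genes the metabolic median was lower by a mean of -0.22 (6 of 6 pairs, exact p = 0.03125), but only 3 sarcomere genes lie below a signal of 5000, so on these genes fewer myocytes and lower expression per myocyte cannot be told apart. A decline of these genes within myocytes is a hypothesis, and whether fibroblast markers rose by more fibroblasts or by more transcript in each stays open.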

How the results depend on the processing

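Signals as deposited and dimmer probe sets first were tested only after the data were seen. Of 546 list calls under alternatives 534 kept their direction and side of the threshold, 7 were lost and 5 gained, and of 1066 values of named genes over the 6 pairs 911 did so, 138 were lost and 17 gained. Of 760 values of named genes in single pairs or models, 630 did so or stayed within the spread between controls, 78 moved beyond it, 51 lost their call and 1 reversed. The floor at the 40th percentile alone moved 57 of these and left 49, and 27 of the 84 genes named for single pairs had an array of the pair at the floor. TAC minus MI stayed at 0 limma calls in all 17 settings (527 at an unadjusted p under 0.05 as reported), and the number of called lists stayed within 1.5 times in 15 of 15. Without the filter on dim genes limma called 0 genes in the common response, 0 for TAC and 0 for MI (3703, 2677 and 2255 at an unadjusted p under 0.05). With that setting the prior degrees of freedom dropped from 5.13 to 1.54 in the common fit and from 4.93 to 1.42 in the fit of separate effects. Without this filter the 2-fold counts were 525 in TAC 1 week and 331 with Ang II, and the median correlation between pairs was 0.117. Above the 60th percentile, where fewer genes are tested, the 2-fold counts were 917, 128 and 138 for TAC at 1 day, 1 week and 1 month, 420 and 170 for MI at 1 week and 1 month and 16 for Ang II, and the hypoxia median in MI 1 week turned to -0.034. The mean of all probe sets gave 694 common, 75 TAC and 60 MI genes. Signals as deposited gave 800 common and 102 TAC genes, and 568 and 669 2-fold genes in TAC 1 week and 1 month. That setting turned the medians of sarcomere genes in TAC 1 month (0.073), glucose metabolism in TAC 1 week (0.022), TAC 1 month (0.10) and MI 1 week (0.0018), and hypoxia in TAC 1 month (0.20). Quantile normalization turned the sarcomere median in TAC 1 month to 0.021, and the floor at the 10th percentile turned Clba1 with Ang II to -0.18. Without the block there were 473 common, 147 TAC and 25 MI genes. Without an intensity trend there were 241 common, 0 TAC and 0 MI genes (2130 and 1665 at an unadjusted p under 0.05), and the unmoderated fit gave 0 common genes (2793). Leaving out each pair gave 256 to 1485 common, 20 to 640 TAC and 0 to 1495 MI genes, the 0 being without MI 1 week (567 at an unadjusted p under 0.05). The 1.5-fold threshold gave 3214, 1070.0, 1045, 2096, 1089 and 551 genes in TAC 1 day, 1 week and 1 month, MI 1 week and 1 month and Ang II, as a lower threshold must give more. Without the control range Ang II had 342. Dimmer probe sets first moved no count of genes or lists by more than 1.5 times. List calls lost were sarcomere (adjusted p = 0.649) and glucose metabolism (0.471) after quantile normalization, atrial markers (0.0542) with the mean of probe sets, neutrophil markers (0.0688) and glucocorticoid-responsive genes (0.0916) without the block, and neutrophil markers without TAC 1 day (0.129) or MI 1 week (0.0946). Gained were ribosomal proteins after quantile normalization (0.000198) and as deposited (0.0426), the circadian list as deposited (0.0422) and without TAC 1 week (0.0304), and MHC class II without MI 1 week (0.00297). Except where stated, the cause was not tested. Signal limits what can be seen at both ends: genes below a signal of 18.1 were not tested, and 152 genes lie above 5000, where probe sets of 1 gene can differ in ratio (Atp2a2 -0.15 in the brightest, -0.58 in 2 dimmer ones and -0.13 in the dimmest).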

Other observations

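The genes in this part outside the list rule were chosen after their values were seen, and no test was run on them.

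Hspa1b and Hspa1a, inducible chaperones, were at 3.16 and 2.49 in TAC 1 day and at 3.45 and 2.90 in TAC 1 month, but at -0.52 and -0.60 in TAC 1 week, -1.21 and -1.25 in MI 1 week, -2.88 and -2.25 in MI 1 month and -1.65 and -0.83 with Ang II. The signals of Hspa1b were 1979.8 and 2551 in the MI-series shams at 1 week and 1 month and at most 357 in the other 4 controls, and those of Hspa1a were 429 and 570.0 against at most 173. The 24 heat shock and unfolded protein genes had a median of 0.45 in TAC 1 day and between -0.14 and 0.060 in the other pairs, and controls differed by up to 0.43.

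The circadian clock list, which did not pass camera (adjusted p = 0.154), had a median of -0.54 in MI 1 week, inside the difference between controls of up to 0.60. Of its 18 measured members 6 were above 0 there. Arntl, a transcription factor of the clock that peaks opposite to Dbp over the day, was at 3.08 and Dbp at -2.16. Times of day at tissue collection are not given in the sources used here. In MI 1 month the adipocyte markers Car3 and Adipoq were at 4.11 and 3.80, but only 3 of the 8 measured adipocyte markers were above 0 there, with a list median of -0.17.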
